A study of Rattus norvegicus with 3 samples.

How the data were processed

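Gene expression was measured in kidney RNA of male spontaneously hypertensive rats in 3 groups: water, and a low and a high dose of a hydrolysate of blue mussel protein. RNA of 4 animals per group was pooled, so each group has 1 array. Groups were taken from the sample labels.

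Each array is an Agilent rat oligonucleotide array hybridised with Cy3-labelled cRNA, per the labels. The deposited scanner files give each spot's intensity at 532 nm, per the file headers, as read by GenePix Pro 6.1.0.4 at a photomultiplier setting of 550. The submitters' processing notes name Agilent Feature Extraction, but the columns are those of GenePix. The authors' software subtracted a background of 39 from the control and high-dose arrays and 40 from the low-dose array, per the file headers, which name the mean of negative controls as its basis. After it the 153 negative control spots of each array still had a mean intensity of 2.29 on the control, 1.30 on the low-dose and 1.89 on the high-dose array. The signal-to-noise ratio and the flag of each spot are deposited as a score, and the saturated pixels of a spot as a percent, per the file headers. The authors also deposited a table of log2 values, with 1 row per probe. Each column of it correlated best with the scanner values of its own array (r of 0.945, 0.950 and 0.957 for control, low and high dose), and all 3 columns had a median of 4.77. Their top values were also equal, at 15.99, while their lowest values were -6.64, -4.98 and -6.64, so the arrays were scaled to each other by a method that is not given in the sources used here.

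All 3 arrays lay on 1 slide, so position on the slide and group cannot be told apart. The header lists a further array of the high-dose group on that slide, which was not analysed here. The header of the high-dose file names a mouse design. All 45220 spots carry the same annotation as on the control array, and the values correlated with the control array at 0.989 over 14537 probes above background, so it was read as the rat design.

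Control spots were left out, as were spots that the software did not find although they were bright (6, 5 and 6 on the control, low-dose and high-dose arrays). Files of this kind hold no outlier flag. Spots whose pixel mean and median differed by over 1.5-fold were therefore left out as non-uniform (166, 139 and 80 spots), a limit set after the data were seen. The net mean intensity of a probe's spots was averaged and scaled so that the 75th percentile was equal on every array (factors 1.14, 0.960 and 0.912). Values were set to at least 1 and expressed as log2. Saturated pixels occurred in 4, 3 and 4 probes, which were kept. A probe counted as above background when at least 50% of its spots had a signal-to-noise ratio of 3 or more. This held for 50.4%, 52.0% and 54.7% of the 30367 probes. The design had been written for Feature Extraction signals and its flag for signals well above background. The net mean and the signal-to-noise ratio took their place, and the 75th percentile scaling was kept.

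Of the probes, 18355 were named through their accession in a RefSeq gene table of the assembly GRCr8, 2758 by a current symbol, 422 through a synonym and 1787 by the symbol in the files, while 7045 had no symbol. No coordinates were used, since the files name no build. A gene was represented by its probe above background on most arrays, then by the brightest. Genes with placeholder symbols were counted separately.

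With 1 array per group, a size rule replaced a test. A gene counted when its probe stood above background on both arrays compared and differed by at least 2-fold. Where it stood above background on 1 array only, an at-least fold was computed against the higher of the dim probe's own value and the lowest value above background on the dim array. The 43 gene lists, chosen before the data were examined, were summarised by the median over members above background on all 3 arrays. Of these, 42 had at least 5 such members and were set against 10000 random lists of equal size matched on mean expression in 20 bins. A list stood apart below percentile 2.5 or above 97.5. The number of lists means that some fall outside this range by chance, and members of a list are not independent.

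Named genes followed a rule set before the data were examined. For each dose against control these were the 10 largest rises and the 10 largest falls among genes that passed the size rule and kept their direction under quantile normalization and normexp. Between doses, the 5 highest and 5 lowest were named, and among genes past 2-fold at both doses the 5 with the largest smaller change. Up to 4 members past 2-fold were named per list, with renin-angiotensin genes named whatever their value and the 2 largest at-least folds per direction and dose. Not every gene that meets the rule is printed. Genes named outside the rule are described as such, apart from the ends of the renin-angiotensin range and Gpd1 and Vegfa, which were picked for their control signal.

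Scaling and counting were tested on simulated data: 9641 genes with the real means, noise of 0.24 (log2) and 200 changed genes, treated against control. The size rule found 94.0% of 50 genes changed 3-fold, 100% of 50 changed 4-fold, 44.0% of 50 changed 2-fold and 8.00% of 50 changed 1.5-fold, and it took 37 of 9421 unchanged genes. A list of 20 genes shifted by 0.5 came out at percentile 100. The noise was the median SD between spots within the control array, drawn separately for each simulated array. No spread between animals or pools was simulated. Spot differences between the real arrays had an SD of 0.17 for the high dose against control and 0.18 for the low dose. These rates therefore test the functions and are not error rates for the real arrays.

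Processing was repeated, as set out beforehand, with quantile normalization, cyclic loess, normexp background correction with an offset of 50, the authors' table, above background on all 3 arrays, no filter on dim probes, the brighter 50% of the probes, the mean over a gene's probes, a threshold of 1.5-fold, lists with dim members and list means. Added after the data were seen were keeping non-uniform spots, the pixel median of each spot, leaving out the weak corner (rows 1 to 20 and columns 1 to 42, drawn by eye), using spots flagged good, and taking background from negative controls (mean plus 2.6 SD). Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and R 4.3.3 with limma 3.58.1, were used.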

Results

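Kidney transcripts were measured in male spontaneously hypertensive rats, a strain with a Wistar background that develops high blood pressure with age. The animals drank a hydrolysate of blue mussel protein, which is a mixture of peptides released from the protein, or water. The low dose was 10 mg/kg and the high dose 20 mg/kg per day, given by mouth for 4 weeks to groups of 10 rats aged 8 to 10 weeks at 280 to 330 g. RNA from 4 rats of each group was pooled and put on an array with a single dye, so the data hold 3 arrays, each of 1 pool. With no replicate of any group, the values below describe these arrays, no test was possible, and the number of arrays limits the precision. Of 30367 probes, 15317 stood above background on the control array, 15794 on the low-dose array and 16605 on the high-dose array. Probes printed on 10 spots had a median SD between spots of 0.24, 0.18 and 0.19 (log2) on the control, low-dose and high-dose arrays. This is technical spread within an array and holds nothing of the difference between animals.

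The comparison of the high dose with control asked which transcripts differ in kidneys of treated animals. Several genes of fat cells stood farthest above control. Scd, the desaturase that makes monounsaturated fatty acids, was 18.7-fold higher. Ucp1, the uncoupling protein of brown fat mitochondria, was 14.8-fold higher, and Thrsp, a regulator of lipogenesis, 12.4-fold. Fabp4, a fatty acid carrier of adipocytes, was 9.17-fold higher and Adipoq, the adipocyte hormone adiponectin, 8.17-fold. Under normexp the log2 differences were 3.42 for Scd, 2.65 for Ucp1, 2.42 for Thrsp, 2.37 for Fabp4 and 2.38 for Adipoq, in place of 4.22, 3.89, 3.63, 3.20 and 3.03. The Scd value comes from a probe with 1 spot, and a different probe with 10 spots gave a log2 difference of only 0.96, so the size of the Scd difference is uncertain. Other large differences were those of Uchl1, a ubiquitin hydrolase, at a log2 difference of 2.78, and Nnat at 2.27. Eif3l at 3.19 and Snx7 at 2.80 also ranked among the 10 largest, but both were printed in a corner of the control array where signal was weak.

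Genes lower at the high dose differed less from control than the higher genes did. Bcl6, a transcriptional repressor, was lowest against control, with a log2 difference of -1.53. Ccn2, a connective tissue growth factor, was at -1.24 with 10 spots, Hsd3b2, a steroid dehydrogenase, at -1.24, and Banp at -1.25. Eif1a stood at -1.20, Klhl25 at -1.13, Gpr35 at -1.11, Tob2 at -1.10, and Map3k6 at -1.09. Under normexp only Bcl6, Ccn2 and Tob2 of these stayed past 2-fold, with Gpr35 at -0.52 and Hsd3b2 at -0.64. Of 9891 named genes above background on both arrays, 84 were at least 2-fold higher and 15 at least 2-fold lower, with a median difference over all of them of -0.04 (log2). Among genes with a placeholder symbol 6 were higher and 2 lower. Under normexp background correction 36 were higher and 3 lower. Without the spots of the weak corner 65 were higher and 15 lower, and with spots of non-uniform signal kept 31 were lower. Among replicate spots of the same probe, 0.279% of spot pairs on these 2 arrays departed from the probe's own median difference by 2-fold or more, and 0.0734% outside the weak corner.

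Gene lists fixed in advance were set against 10000 random lists of equal size and similar expression. At the high dose 12 lists lay above and 5 below the central 95% of random lists. Adipocyte markers led, with a median log2 difference of 1.06 and 7 of 13 measured members at least 2-fold higher, among them Cidea at 1.47 and Pparg at 1.06. Fatty acid synthesis genes as a list did not stand apart (median 0.00, percentile 79.7; by the mean, 0.51, percentile 100), with 11 of 20 members above control and 4 past 2-fold. Tubule segments differed in direction. Thin limb markers had a median of 0.95 over 6 measured members, 4 above and 2 below control, with Akr1b1, the aldose reductase that makes sorbitol, at 2.19, the urea transporter Slc14a2 at 1.68 and Cldn4 at 1.07. Collecting duct principal cell markers had a median of 0.57, with 8 members above and 5 below control and 1 of 13 past 2-fold, which was Slc14a2 again. Under normexp their median was 0.07, at percentile 97.1, inside the range of random lists. The water channel Aqp2 stood at 0.62 and Fxyd4 at 0.95. Proximal tubule markers had a median of -0.33, with 22 of 28 members below control and none past 2-fold. Drug-metabolising enzymes and transporters (median -0.33, 32 of 41 below control) and amino acid and peptide transport (-0.29, 25 of 33) lay low as well, and both lists hold many proximal tubule genes. Sodium and potassium transport genes had a median of -0.24, with 23 of 36 below control. Over the mean in place of the median, amino acid transport moved to percentile 6.91 and sodium and potassium transport to 3.10, inside the range of random lists.

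Immediate early genes, which respond within minutes to handling and stimulation, had a median of 0.38 at the high dose, with Klf10 at 1.16 and Egr1 at 1.04. Tubular injury genes had a median of 0.46, with 2 of 21 past 2-fold: S100a6 at 1.43 and Gpnmb at 1.02, the latter at 0.32 under normexp. Extracellular matrix genes had a median of 0.19 with 0 of 30 at least 2-fold higher and 1 lower, Ccn2. Smooth muscle and pericyte markers had a median of 0.18, with Actg2 at 2.08 and Tagln at 1.14, and lay inside the range of random lists under normexp (percentile 91.6). Glucocorticoid-responsive genes lay low, with a median of -0.34 and 14 of 17 members below control. Errfi1 was at -1.01; Sgk1, Fkbp5 and Tsc22d3, named after their values were seen, were at -0.97, -0.87 and -0.52. Ribosomal protein genes (median 0.01) and respiratory chain genes (-0.02) lay above random lists because genes as bright as these lay below 0, and respiratory chain genes came inside the range with the mean over a gene's probes (percentile 96.5). Blood cell markers had a median of 0.16, which lay inside the range of random lists under quantile normalization (percentile 97.1).

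**Figure D1:**
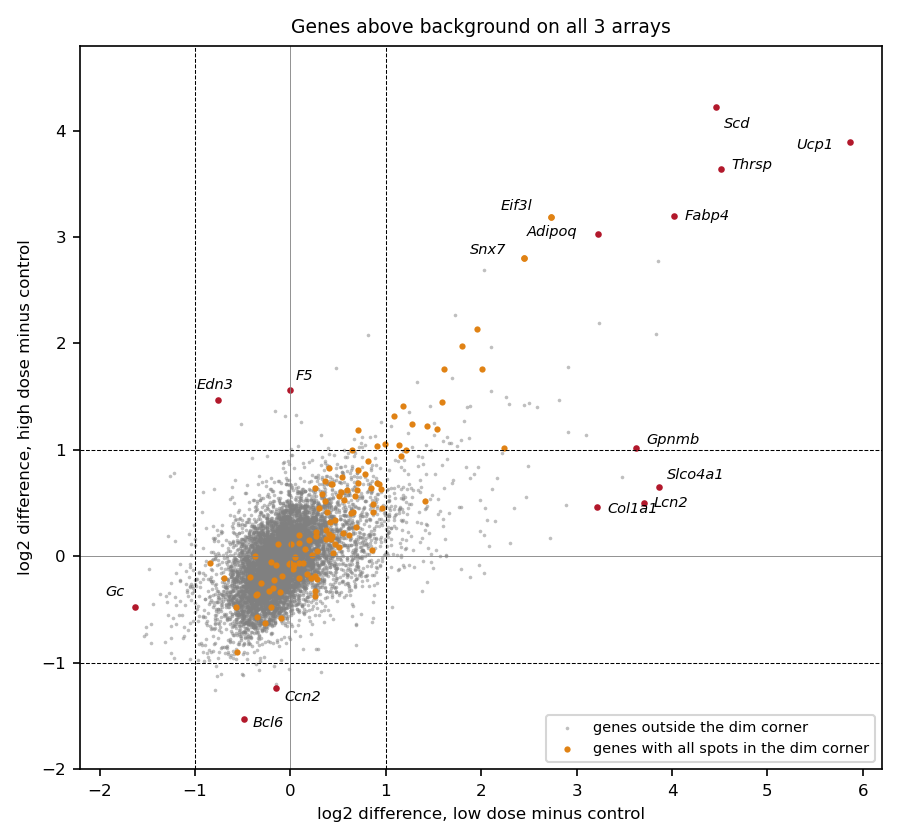
Log2 difference from control at the low dose (horizontal axis) and at the high dose (vertical axis) for each of the 9641 named genes above background on all 3 arrays, with dashed lines at 2-fold. Scd, Ucp1, Thrsp, Fabp4 and Adipoq lie far to the upper right, Lcn2, Gpnmb, Slco4a1 and Col1a1 lie far to the right near the dashed line or below it, and orange points mark genes printed in the weak corner of the control array.

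The low dose differed from control in more genes than the high dose did on these arrays. Ucp1 was 58.2-fold higher than control, Thrsp 22.8-fold, Scd 22.0-fold and Fabp4 16.3-fold. The control signal of these genes was dim, and under normexp the log2 differences were smaller: 4.53 in place of 5.86 for Ucp1, 3.22 in place of 4.51 for Thrsp, 3.64 in place of 4.46 for Scd and 3.14 in place of 4.02 for Fabp4. Cox8b, a respiratory chain subunit of muscle and brown fat, was 14.2-fold higher, and Uchl1 14.5-fold. Slco4a1, an organic anion carrier, was 14.6-fold higher. The tubular injury genes Lcn2, a lipocalin released by injured tubules, and Gpnmb stood at a log2 difference of 3.70 and 3.63. The spot behind the Scd value was not flagged good on the low-dose array, and the other probe again gave a smaller log2 difference, 0.90.

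Genes lower at the low dose also differed less than the higher genes. Gc, the vitamin D-binding protein, stood at -1.63 (log2), Cyp24a1, which degrades active vitamin D, at -1.48, and the organic cation carrier Slc22a2 at -1.31. Slc22a24 was at -1.51, Dhrs7l1 at -1.37, the guanylate cyclase subunit Gucy1b2 at -1.46 and the chloride channel Cftr at -1.44. Sspo stood at -1.53, Lmbrd2 at -1.51 and Gcm1 at -1.46. Of 9734 named genes above background on both arrays, 243 were at least 2-fold higher and 65 at least 2-fold lower, while the median over all of them was -0.11. Among genes with a placeholder symbol 13 were higher and 9 lower. Under normexp 135 were higher and 21 lower. Replicate spot pairs departed from their probe's median difference by 2-fold or more in 0.371% of cases, and in 0.0736% outside the weak corner.

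At the low dose 18 lists lay above and 8 below the central range of random lists. Extracellular matrix and fibrosis genes had a median of 1.11, with 17 of 30 measured members at least 2-fold higher and 0 lower. The collagens Col1a1, Col15a1 and Col3a1 stood at 3.21, 2.30 and 2.15, and the matrix protease Mmp2 at 2.34. A different probe of Col1a1 gave a smaller difference, 2.18. Tubular injury genes had a median of 1.14, with 12 of 21 at least 2-fold higher, including Clu at 2.89 and S100a6 at 2.29, and 1 lower. Macrophage and dendritic cell markers lay high too, with a median of 0.72 and 19 of 20 members above control. Clec10a was at 2.08, the complement subunits C1qc and C1qa at 1.26 and 1.23, and Cd14 at 1.18. T, NK and B cell markers had a median of 0.53 over 9 measured members, with Cd3g at 1.19 and Cd7 at 1.16.

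Inflammatory cytokines and chemokines had a median of 0.37 at the low dose, with 25 of 29 members above control and 6 past 2-fold. The monocyte chemokine Ccl2 was 5.65-fold higher, and Ccl3 stood at 1.52, Il1b at 1.46 and Cxcl10 at 1.16. Under normexp the last 3 stood at 0.76, 0.67 and 0.76. At the high dose the list had a median of 0.04, inside the range of random lists (percentile 87.1), but lay above it by the mean (98.3). Ccl2 at 1.44 and Il1b at 1.41 passed 2-fold there, with 0.66 and 0.55 under normexp. Interferon response genes at the low dose had a median of 0.48 with 22 of 29 above control, of which Cxcl10 and Ifitm3 (1.09) passed 2-fold. Complement and coagulation genes had a median of 0.19, with 7 of 27 at least 2-fold higher, led by C3 at 1.56. Cell cycle genes had a median of 0.20, and Cdk1 at 1.15 was the member past 2-fold. Immediate early genes had a median of 0.35, with Atf3 at 1.38 and Klf10 at 1.24. Ribosomal protein genes had a median of 0.08 and endothelial markers of 0.26. Smooth muscle and pericyte markers had a median of 0.41, and Tagln was 2.83-fold higher. In the brighter part of the probes, cell cycle genes (percentile 76.3) and endothelial markers (72.6) lay inside the range of random lists.

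Adipocyte markers had a median of 1.68 at the low dose, with 7 of 13 members at least 2-fold higher, and fatty acid synthesis genes 0.17, with 5 of 20. Among the latter were Fasn, the fatty acid synthase, at 2.91 and Agpat2 at 1.28. Fatty acid oxidation and PPAR target genes split: the median was -0.23, and 37 of 51 members lay below control, but 6 were at least 2-fold higher, among them Cidea at 2.81, Angptl4 at 2.04 and Pparg at 1.68. By the mean, 0.05, the same list lay at percentile 97.7, on the opposite side of random lists, and with the authors' values it lay inside their range (6.27). Thin limb markers (median 1.21, 4 of 6 above control, Akr1b1 at 3.23, Cldn4 at 1.66) and principal cell markers (0.73, 8 of 13 above control, Slc14a2 at 1.69, Aqp2 and Fxyd4 at 1.34) lay high, as at the high dose. Proximal tubule markers lay low, with a median of -0.38, 25 of 28 members below control and Slc7a13, an amino acid carrier, at -1.29. Drug-metabolising genes (median -0.42, 4 of 41 at least 2-fold lower) included Cyp2d5 at -1.26, Slco1a6 at -1.01 and, at the 2-fold line, Slco1a1. Amino acid and peptide transport (median -0.39, 5 of 33) included the peptidases Mep1b at -1.25 and Cndp1 at -1.21 and the carrier Slc7a12 at -1.22.

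The direct comparison of the doses asked where a larger dose gave a different level. On these arrays, most named genes above background at both doses that passed 2-fold were lower at the high dose. A2m, the protease inhibitor alpha-2-macroglobulin, stood lowest at the high dose against the low dose, at -3.83, followed by Slco4a1 at -3.22, Lcn2 at -3.20 and Col1a1 at -2.75. A different probe of Col1a1 gave -1.61. Edn3, the peptide endothelin 3, was highest at 2.23, followed by Nrn1l at 2.02, the amino acid carrier Slc7a12, which was 4.01-fold higher, Smim5 at 1.76 and coagulation factor F5 at 1.57. Under normexp Edn3 at 0.93 and F5 at 0.84 fell below 2-fold. Slc7a12 at 1.52, Nrn1l at 1.32 and Smim5 at 1.31 then stood above Edn3. At the low end A2m at -2.49 then came behind Slco4a1 at -2.90. Of 10137 named genes, 47 were at least 2-fold higher and 150 at least 2-fold lower at the high dose. Under normexp the counts were 16 and 71. Extracellular matrix genes had a median of -1.01 between the doses, with 15 of 30 at least 2-fold lower at the high dose, tubular injury genes -0.86, macrophage markers -0.72 and interferon response genes -0.47. Glucocorticoid-responsive genes also lay lower at the high dose, with a median of -0.52. Thick ascending limb markers had a median of 0.67 between the doses, and all 11 measured members were higher at the high dose.

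**Figure D2:**
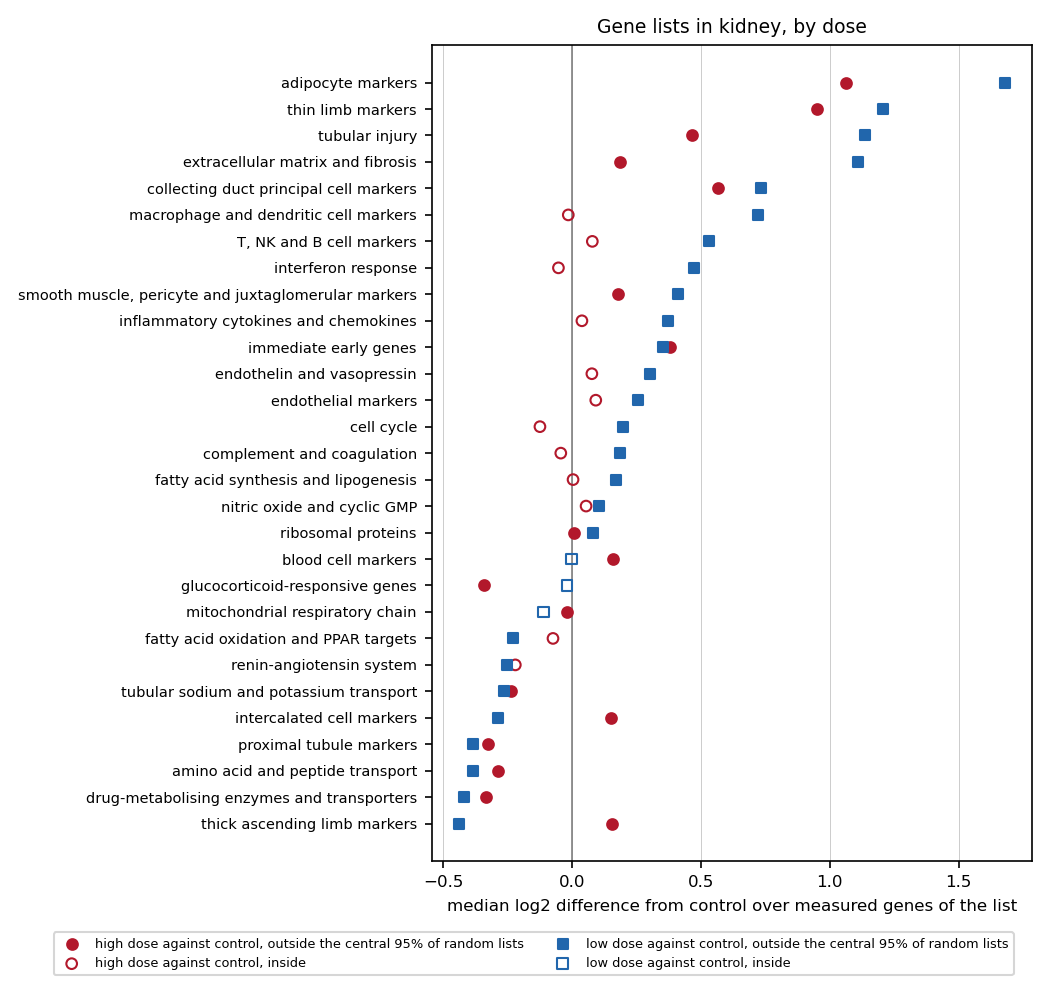
Median log2 difference from control (horizontal axis) of each of the 29 gene lists that lay outside the central 95% of random lists at a dose, with red circles for the high dose and blue squares for the low dose. Filled symbols lie outside that range and open symbols inside; adipocyte markers are highest at both doses, at 1.06 and 1.68, and extracellular matrix genes differ most between doses, at 0.19 and 1.11.

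Both doses shared a set of higher genes. Scd, Ucp1, Thrsp, Fabp4 and Adipoq had the largest smaller-of-both differences. In all, 58 of 9641 genes above background on every array were at least 2-fold higher at both doses, and 0 were at least 2-fold lower at both or past 2-fold in opposite directions. The absence of genes lower at both depends on leaving out spots of non-uniform signal, a limit set after the data were seen, since 11 were lower at both when these were kept. Of the 58, 15 had all their spots in the weak corner of the control array, against 1.12% of measured genes, which leaves 43. Independent lists of these sizes would share 2.11 higher genes and 0.0944 lower genes. Because both comparisons use the same control array, the arrays were also exchanged at random within each gene 1000 times, which keeps real differences in the spread. This gave on average 25.9 higher genes at both doses (upper end of the central 95% 34.0) and 32.8 lower genes (upper end 42). In opposite directions the exchange gave 4.39. With higher and lower genes counted jointly, the 58 observed genes were no more than the exchange gave on average. What differed was the direction, since 0 of the observed genes were lower at both doses. With each array in turn as the shared reference, the control array was at least 2-fold below both others in 58 genes and above both in 0. The low-dose array was above both others in 93 and below both in 14. The high-dose array was above both in 10 and below both in 5.

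**Figure D3:**
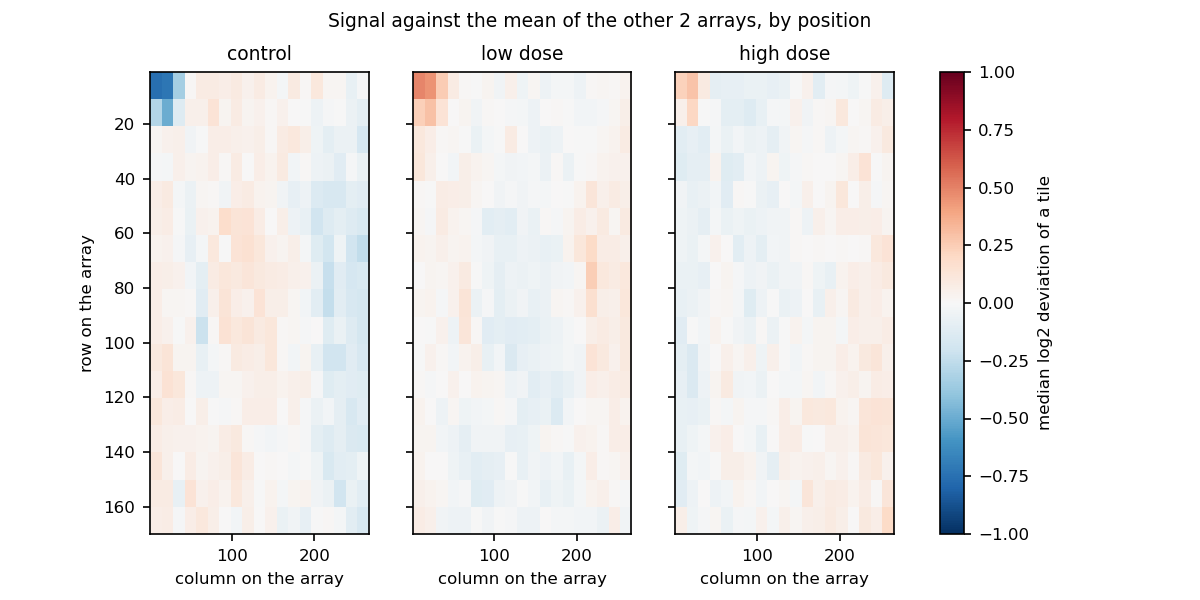
Signal of each array against the mean of the other 2, as the median log2 deviation of spots in tiles over the array surface (columns across, rows down; blue dimmer, red brighter). The upper left corner of the control array is dim, down to -0.76 in a tile, and the same corner is brighter on the other arrays because the control array is part of their comparison.

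Across genes, which are not independent replicates, the log2 differences at the doses had a Pearson correlation of 0.59, against 0.50 on average after the exchange. The covariance was 0.0897 against 0.0745, a difference of 0.0152. Part of any excess may come from the shared control array, since 1 array cannot be split.

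Genes of blood pressure control were examined as lists, because the treated strain is hypertensive. In the renin-angiotensin system the 18 measured members had a median of -0.22 at the high dose and -0.25 at the low dose. The low-dose median lay at percentile 2.42, and at 41.4 when members not above background were included. The high-dose median lay at percentile 3.45, inside the range of random lists, but below it in that alternative (2.09) and with the mean over a gene's probes (1.88). The angiotensin-converting enzyme Ace stood at -0.27 and -0.35 at the high and low dose. Angiotensinogen (Agt) stood at -0.43 and -0.81, and the receptor Agtr1a at 0.16 and 0.22. The peptidase Mme, at -1.10 at the low dose, was the member past 2-fold. Members ranged from -0.71 (Agtrap) to 0.77 (Rnpep) at the high dose and from -1.10 to 0.47 (Klk1) at the low dose.

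Among genes of endothelin, vasopressin and adrenergic signalling, 3 of 18 were at least 2-fold higher at the low dose: the adrenergic receptor Adra1d at 2.72, the receptor partner Ramp1 at 1.82 and Aqp2. At the high dose Ramp1 at 1.27 and Edn3 at 1.47 passed 2-fold, but under normexp they stood at 0.88 and 0.59. A different probe of Ramp1 gave 0.36 at the high and 0.45 at the low dose. The median was 0.30 at the low dose, above random lists, and 0.08 at the high dose, inside their range. With members not above background included, the low-dose median was 0.01 (percentile 97.0), inside the range, and the high-dose list stood above it with the authors' values (98.1) and by the mean (99.9). Nitric oxide and cyclic GMP genes had a median of 0.11 at the low dose, with Cav1 at 1.03 and Gucy1b2 at -1.46, and their mean of -0.01 had the opposite sign; under normexp the list lay inside the range of random lists (percentile 93.8). Sodium and potassium transport genes had a median of -0.26 at the low dose, with 28 of 36 below control. Fxyd4 at 1.34 was the member past 2-fold at the low dose and Slc4a7 at 1.12 (0.24 under normexp) at the high dose.

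Some genes stood above background on 1 array of a comparison and not on the other, which gives a bound as defined above. Where the dim probe's own value was the higher, as for Hsd3b2 at the low dose, this is a plain ratio to that value and no strict limit. At the high dose Nrg2 was at least 20.4-fold and the adipocyte hormone Retn at least 19.1-fold higher than control, while Tktl2 was at least 1.91 (log2) and Atxn1l at least 1.32 (log2) lower. At the low dose the matrix protease Mmp7 was at least 59.0-fold and A2m at least 25.6-fold higher, while Hsd3b2 was at least 4.50-fold and Spmip4 at least 2.87-fold lower. Such bounds hold in the chosen processing only. Under normexp A2m stood at 2.66 and Hsd3b2 at -0.78 (log2) at the low dose, both smaller than these bounds. Bounds of 2-fold or more were found for 56 higher and 7 lower genes at the high dose, and for 123 higher and 36 lower genes at the low dose, with 58 higher and 49 lower at the high dose against the low dose.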

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

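Of the tests in this part, those of the corner's brightness, of the corner's part in the fat cell genes, of fatty acid synthesis alone, of adipose genes silent in control, of the pools and of a lower proximal tubule share were chosen after the result was seen.

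Markers of the thick ascending limb lay on opposite sides of control at the doses, which is why they are raised here. Their median lay at 0.16 at the high dose (percentile 99.2) and at -0.44 at the low dose (percentile 0.08), a difference of 0.67 in the direct comparison. Intercalated cell markers likewise had a median of 0.15 at the high dose and -0.28 at the low dose, where 14 of 14 members lay below control, a difference of 0.38. The high-dose side of the intercalated cell list lay inside the range of random lists under quantile normalization (percentile 97.4) and in the authors' table (77.8). Neither difference was tested, since each group has 1 array.

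Among the genes higher at both doses, 15 were printed in a corner of the control array, among them Eif3l and Snx7. Over 170 probes printed on 10 spots with some of them in that corner, spots inside were dimmer than spots outside by a median of -0.45 (log2) on the control array, against -0.0017 on the low-dose array and -0.11 on the high-dose array. Weak signal in that corner is therefore a likely source of these differences. The median dimming was nevertheless smaller than the 2-fold that each of these genes passed. The largest over these probes was -2.53 on the control array, against differences of 3.19 and 2.73 for Eif3l at the high and low dose. A change in the transcripts stays open, because 0 probes of these genes lie outside the corner and above background on all arrays.

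Fat cell genes stood higher at both doses: of the 7 adipocyte markers past 2-fold at both doses, 0 lay in the weak corner, which argues against that source. A rise of fatty acid synthesis in kidney cells alone stays open, since the 10 measured adipocyte markers outside the fatty acid synthesis list had a median of 0.997 at the high dose and 1.08 at the low dose, more than this source needs but not past the bound of 1 at both doses, with a wide spread between members (SD 1.44 and 2.09). Fat carried with the treated kidneys failed the test set beforehand: 11 measured adipose genes outside the fixed lists lay at percentiles 47.9 and 75.1 at the high and low dose, under the bound of 90 stated as counting against it. That bound was wrong by design, which was seen only afterwards, since it covers genes that kidney expresses itself (Gpd1 3573 and Vegfa 1398 scaled intensity units in control), whose level would hide a small share, so this source stays open. Of the 11 adipose genes not above background in control, 6 at the high dose and 5 at the low dose stood above it. These are 54.5% and 45.5%, against 12.1% and 9.27% of all such genes, which were not matched on intensity. Some barely differed from control, such as Ebf1 at 0.04 and Trarg1 at 0.38 (log2) at the high dose. By their plain values 4 of those above background at each dose were at least 2-fold higher. Among them Rbp7 had 26.5 scaled units at the high dose against a control value set to 1. Since the lowest value above background in control was 13.7, Rbp7 has no bound of 2-fold there. With 1 pool per group a chance difference between pools cannot be told apart from treatment.

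By their medians, thin limb and principal cell markers stood higher and proximal tubule markers lower at both doses, although under normexp the high-dose principal cell list lay inside the range of random lists (percentile 97.1). A lower share of proximal tubule alone would raise other segments alike, which the gap of 1.17 between principal cell and thick ascending limb medians argues against at the low dose (0.66 under normexp). It stays open at the high dose, where that gap was 0.41, and where principal cell and distal tubule medians lay 0.85 apart but 0.25 under normexp. The weak corner is argued against too, since without it the smallest of the medians of thin limb and principal cell markers was 0.57. More inner medulla in the treated samples may account for part of the pattern. Over 18 measured inner medulla genes outside the fixed lists, the median was 0.52 at the low dose (percentile 100). Of these, 11 lay above control there and 4 were at least 2-fold higher. Named after their values were seen, the 4 were S100a4 (1.97), Smoc2 (1.47), Tspan1 (1.42) and Fxyd5 (1.18). Others lay below control at the low dose, such as Ppp1r1b at -0.80 and Slc39a8 at -0.76. At the high dose the median was 0.09 (percentile 98.5, 12 above control, 0 of 18 at least 2-fold higher), far below the principal cell and thin limb medians there. A response of these cells to treatment stays open, untested.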

How the results depend on the processing

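The tests with non-uniform spots kept, the pixel median, the corner left out, spots flagged good and negative controls were chosen after the result was seen. No paired analysis was possible because each group has 1 array. Counts are given in the order high dose against control, low dose against control, and high against low dose, each as higher and lower genes. Under normexp they were 36 and 3, 135 and 21, and 16 and 71, with 27 higher at both doses. In the brighter 50% of the probes they were 41 and 9, 109 and 32, and 18 and 53, with 32 higher at both. At a threshold of 1.5-fold they were 368 and 375, 654 and 442, and 409 and 560, with 189 higher and 97 lower at both and 10 in opposite directions. With no filter on dim probes they were 1040 and 952, 948 and 1695, and 1583 and 690, with 416 higher and 566 lower at both and 86 in opposite directions; probes at background enter there. With the authors' values, 29 genes were lower at the high dose, and with quantile normalization 1 was lower at both doses. Keeping non-uniform spots, whose limit was itself set after the data were seen, gave 31 lower at the high dose and 11 lower at both. The pixel median gave 1 in opposite directions. Background from negative controls gave 137 and 44 at the high dose, 118 lower at the low dose, 96 higher between doses, and 91 higher and 6 lower at both. Beyond the construction of each alternative, the cause was not tested. All other counts lay within 1.5 times the main count, and the correlation within 0.1 of its main value.

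Fatty acid oxidation and PPAR targets at the low dose moved from percentile 0.58 to 97.7 with the mean of members, because a few large rises weigh in a mean. Among recomputed percentiles of lists that stood apart, 562 stayed apart in their direction, 36 came inside the range and 1 turned, while 34 percentiles of lists that had not stood apart moved outside it. Among recomputed differences of named genes past 2-fold, 1444 stayed past it and 64 kept their sign below it, 46 of them under normexp, which shrinks dim probes. These included, at the high dose, Banp, Hsd3b2, Eif1a, Klhl25, Gpr35, Map3k6, Gpnmb, Edn3, Smim5, F5, Slc4a7, Ramp1, Ccl2, Il1b, Pparg, Agpat2, Klf10, Egr1, Errfi1, Cldn4 and Tagln. At the low dose they included Nnat, Lmbrd2, Gcm1, Cftr, Nrn1l, Slc7a12, Cav1, Ccl3, Il1b, Cxcl10, Ifitm3, C1qc, Gclm, Slco1a6, Slco1a1, Agpat2, Cdk1, Atf3, Klf10, Cd14, Cd3g, Cd7 and Npy. Corner genes have no value without the corner. Dim control signal limits the largest folds: Ucp1 had 37.4 scaled units in control.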

Other observations

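The genes with bounds in this part were chosen after their values were seen, and no test was run on them. Their bounds hold in the chosen processing only. For Upk3a, Sprr1a, Cfd and Bcat1 the control probe's own value was the higher, so the at-least fold is a plain ratio to it and no strict limit. Urothelial genes stood above background in treated pools and not in control: Upk3a was at least 12.1-fold higher at the high dose and at least 19.6-fold at the low dose, and Upk2 at least 7.72-fold at the high dose. Upk1a, measured on all arrays, stood at 1.55 and 2.10 (log2) at the high and low dose. Sprr1a, a squamous epithelial protein, was at least 7.69-fold and 13.3-fold higher, and Fxyd3 at least 7.06-fold and 17.2-fold. The list of lymphatic and urothelial markers as a whole had medians of 0.15 and 0.11 over 8 measured members, which leave out Upk3a and Upk2, inside the range of random lists at both doses. It stood above that range under several alternatives, such as normexp at the low dose (percentile 98.3) and background from negative controls at the high and low dose (99.9 and 100).

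Further genes of fat and injury had bounds. Cfd, the adipocyte protease adipsin, was at least 15.1-fold higher at the high dose and at least 25.6-fold at the low dose. Car3, abundant in fat, and the beta-3 adrenergic receptor Adrb3 were at least 7.39-fold and 5.39-fold higher at the high dose, and the glycogen synthase Gys2 at least 5.46-fold and 12.2-fold at the high and low dose. Havcr1, the injury protein known as KIM-1, was at least 16.3-fold higher at the low dose, and Bcat1 at least 13.9-fold.

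Other lists inside the range of random lists at both doses in the chosen processing, given as medians at the high and low dose, were kallikrein-kinin genes (-0.23 and -0.23), arachidonic acid metabolism (0.02 and -0.22), antioxidant and NRF2 targets (-0.15 and -0.18) and NADPH oxidase (-0.26 and -0.04). Among them were also cholesterol biosynthesis (0.01 and -0.09), glycolysis and gluconeogenesis (-0.10 and -0.18), heat shock and unfolded protein response (-0.00 and -0.01) and circadian clock genes (0.05 and -0.18). The cell type lists inside the range were distal convoluted and connecting tubule (-0.28 and -0.23), podocyte (-0.15 and -0.11), adrenal (0.03 and -0.26) and liver markers (-0.24 and -0.21). Some left the range under an alternative: at the high dose NADPH oxidase (percentile 0.595 with the authors' values), liver markers (1.27 under normexp), podocyte markers (1.59) and arachidonic acid metabolism (98.5) with dim members, heat shock genes (98.0 with the mean over probes) and distal tubule markers (1.15 without the weak corner). At the low dose these were arachidonic acid metabolism (0.11 in the brighter 50% of probes), NADPH oxidase (99.3 with dim members) and adrenal markers (0.39 with negative controls). Members past 2-fold in these lists included Ptgs1 at 1.64, Gpx2 at 1.47, Gclm at -1.20, Gclc at -1.13, Hspa1b at 1.54, Cdkn1c at 1.44 and Npy at 1.02 (a different probe 0.50), all at the low dose. Granulocyte and mast cell markers had 4 measured members, with medians of 0.00 and -0.25 and no percentile. Blood cell markers at the low dose had a median of -0.00, with Pf4 at 1.61.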
